A study of Mus musculus with 20 samples.

How the data were processed

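Total RNA of liver tissue was isolated with a column kit and made into strand-specific mRNA libraries, per the labels' protocols. The authors deposited a table of raw counts per Ensembl mouse gene and a table of TPM values. Reads were counted with featureCounts 1.4.6-p1 and aligned with HISAT2 1.2.1, per the submitters' processing notes. Those notes list the human build GRCh38 although the gene identifiers are mouse, so the build used for the counts is not clear; the annotation version and strand setting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be assigned with certainty. The deposited counts are whole numbers that differ in total between libraries. The deposited TPM values are counts per kilobase of gene length scaled to the same sum in each library: over 7109 genes with more than 200 counts in every library, count over TPM, after 1 factor per library, had a relative SD between libraries of at most 1.10e-09. The header of the TPM table stands 1 cell to the left of its values, and each of its 20 columns followed the counts of its own library best. Of 55493 TPM rows 269 had no symbol.

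Libraries were grouped by their labels. The labels of 10 libraries give a feeding state and no genotype, which was read as Plin2-/- by elimination from the design text and not from any count. The number in the title differs between all libraries. Within groups, 40 pairs of libraries were compared by a chi-square test over genes with a summed count above 20; the smallest chi-square per degree of freedom was 45.3, so no pair agreed within sampling noise and every library counted as 1 replicate. Gene symbols came from a reference table of gene names, in which 55141 of 55487 identifiers matched. Positions, transcript lengths and GC content came from GENCODE M21 (GRCm38).

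Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered by filterByExpr, scaled by TMM and fitted with glmQLFit (robust) over all 20 libraries with 1 coefficient per group. The 4 pairwise comparisons and the interaction, the genotype difference in fasted minus that in fed mice, were tested with glmQLFTest at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the square root of F. CPM values are TMM-scaled. Gene lists, 44 in number, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists of a comparison. Lists, comparisons, tests and the rule for single genes were fixed before the data were examined. The rule took Plin2; per comparison the 8 genes rising and the 8 falling most among those called, with a mean of at least 5 CPM, no overlap between the libraries compared and a symbol that is not a predicted-gene name; up to 4 members of each list holding a called gene, with the smallest adjusted p and any member where a list is described; and the substrain-variable genes and Xist. Some genes that the rule takes are not reported here.

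Alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library size alone, no filter and a stricter filter on low counts, limma on log2(TPM + 1) and log2(TPM + 0.1), a fit on the compared groups alone and leaving out each library in turn. The share of 18S rRNA-like counts as a covariate and the removal of each library's trend with GC content were added after seeing the data. A change of sign counted as such where the result passed its threshold under either setting. Total counts of 25506471 to 65579038 per library set the counting precision, and the spread between animals limits the tests. The fits were tested on simulated counts drawn from negative binomial distributions with the fitted means, spread and library sizes of the real data, with genes changed by known folds: for genotype in fasted mice, 20.9%, 53.7% and 97.0% of 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold were recovered among 16133 genes, with 4 false calls. The simulation drew each gene independently, without a trend of single libraries with GC content or other effects shared between genes. Its recovery and false calls therefore need not hold for the real libraries, where such a trend was seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.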

Results

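RNA was sequenced from liver tissue of female mice, 15 weeks old, on the C57BL/6N background, which either had chow or had been fasted for 24 h. PLIN2 (perilipin 2) is a protein that coats cytosolic lipid droplets. The 20 libraries fell into 4 groups of 5: Plin2+/+ fed, Plin2+/+ fasted, and a fed and a fasted group whose labels give no genotype. The design text names Plin2+/+ and Plin2-/- mice only, so the 10 libraries without a genotype were read as Plin2-/- by elimination and are called Plin2-null here. Total counts per library ran from 25506471 to 65579038, and 16312 genes were tested. Titles give each library its own number, and no label ties these to animals, a batch, a litter or a day, so p-values measure the spread between these samples.

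The targeted gene was examined first. Plin2 (ENSMUSG00000028494) lies on chromosome 4 from 86648386 to 86670060, on the minus strand, in the GENCODE M21 annotation of GRCm38, where it is a protein-coding gene. Its CPM values (counts scaled to the TMM-adjusted library size) were 260 ± 58.2 in Plin2+/+ fed and 19.7 ± 6.96 in Plin2-null fed livers (SD, n = 5 each). After fasting they were 1494 ± 240 and 90.5 ± 22.6 (SD, n = 5 each). Every Plin2-null library lay below every Plin2+/+ library of the same feeding state, a 13.2-fold difference in fed and a 16.5-fold difference in fasted mice. The exact two-sided permutation p was 0.00794 in each state, the smallest that 5 libraries against 5 can give. Plin2 reads were not absent from the Plin2-null libraries, which held 689 to 1463 counts in the fed and 2155 to 6318 in the fasted state. These residual reads rose 4.59-fold on fasting, against 5.74-fold in Plin2+/+ livers. On the log2 scale the genotype difference did not change detectably with feeding (interaction -0.32 ± 0.28 SE, edgeR adjusted p = 0.609). The part of the gene that was targeted is not given in the sources used here, so which exons the residual reads come from was not analysed here.

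**Figure D1:**
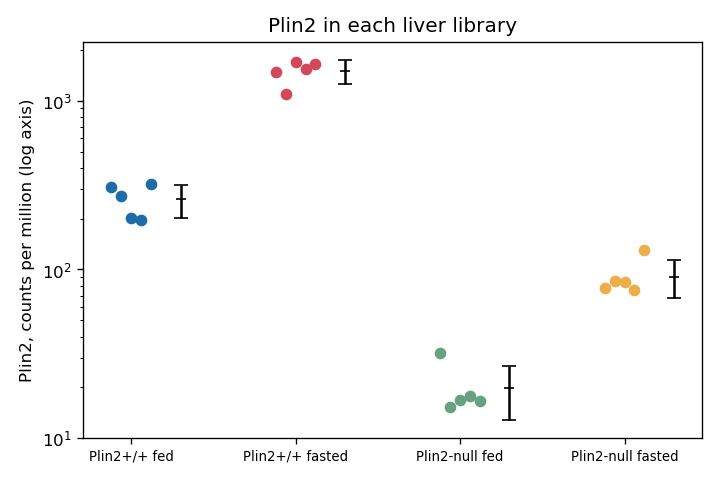
Plin2 CPM (log axis) in each of the 20 libraries, by group; points are libraries and the bar beside each group is its mean with the SD. The Plin2-null fed libraries sit between 15.3 and 32.1, below the Plin2+/+ fed range of 196 to 319.

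Feeding state was the main axis of variation. The first principal component of log2 CPM held 49.4% of the variance and separated all fed from all fasted libraries, while the next held 9.28%.

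**Figure D2:**
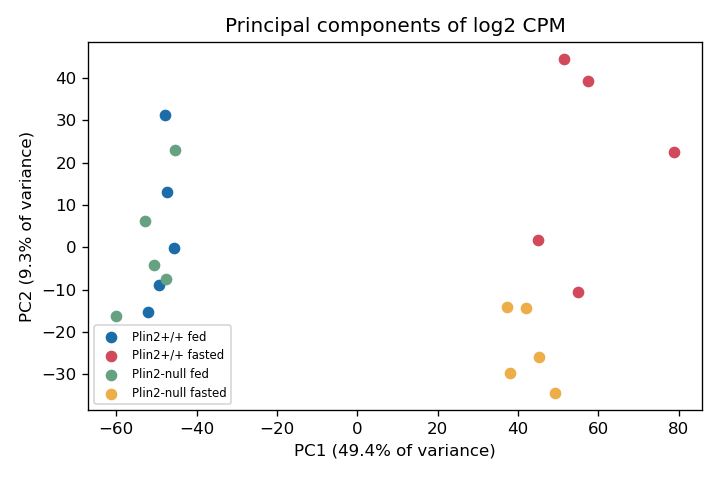
First and second principal components of log2 CPM over the 16312 genes tested, one point per library, coloured by group; axes give the share of variance. All fed libraries lie at negative values of the first component and all fasted libraries at positive values.

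The first comparison asked how the liver of Plin2+/+ mice responds to fasting. Genes of fat oxidation rose and genes of sterol and fatty acid synthesis fell. Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 305 ± 27.0 to 1024 ± 120 CPM (SD, n = 5). Ehhadh, a peroxisomal beta-oxidation enzyme, rose from 341 ± 96.7 to 3966 ± 760 CPM (SD, n = 5). Sqle, an enzyme of sterol synthesis, fell from 85.9 ± 23.5 to 2.77 ± 0.623 CPM, and the lipogenic regulator Srebf1 from 133 ± 33.4 to 5.12 ± 2.08 CPM (SD, n = 5). In all, 6957 genes were called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 3416 higher and 3541 lower in fasted mice, and 2453 of them changed by at least 1 on the log2 scale. With library size alone as the scaling, 1854 rose and 4173 fell, with a shift of the median log2 fold change of all genes of -0.16. On the deposited TPM values, limma called 1494 higher and 3161 lower.

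By group, 14 of 18 genes of mitochondrial fatty acid oxidation and 17 of 19 genes of peroxisomal and omega oxidation rose, and none of either list fell. Adjusted over the list alone, the counts were 14 and 17. Members were Acadm (1.79 ± 0.11 SE on the log2 scale) and Cpt1a (1.75 ± 0.11) of the first list, and Ehhadh (3.54 ± 0.18) and Pex11a (2.69 ± 0.15) of the other. camera gave adjusted p = 2.64e-10 and 2.92e-11 for these lists, and adjusted p = 0.159 and 0.159 with an estimated correlation. fry gave adjusted p = 1.41e-08 and 2.36e-08 for them, and called 28 of the 44 lists in this comparison. Of 14 gluconeogenesis genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00156 and adjusted p = 0.302 with an estimated correlation. Slc37a4, the glucose-6-phosphate transporter, rose by 1.62 ± 0.19.

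Sterol synthesis and uptake fell: 24 of 25 members fell and none rose, also when adjusted over the list alone, with a median log2 fold change of -2.81 (camera adjusted p = 7.95e-21; adjusted p = 0.159 with an estimated correlation). Fdps changed by -5.94 ± 0.44, Mvd by -5.46 ± 0.43, Sqle by -4.97 ± 0.36 and Insig1 by -3.75 ± 0.27 (log2, SE). Of 18 fatty acid synthesis genes 14 fell and 3 rose, among them Srebf1 (-4.70 ± 0.29), Acly (-2.67 ± 0.22) and Fasn (-3.06 ± 0.30), with camera adjusted p = 2.62e-06 and adjusted p = 0.182 with an estimated correlation. Adjusted over the list alone the counts were 14 and 3.

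Genes of the lipid droplet moved the other way. Of 21 lipid droplet proteins and lipases, PLIN2 left out, 11 rose and 1 fell (12 and 1 adjusted over the list alone). Cidec, a droplet fusion protein, went from 0.228 ± 0.114 to 55.6 ± 31.6 CPM, and Plin5, which coats droplets in oxidative tissues, from 13.5 ± 3.09 to 105 ± 32.9 CPM (SD, n = 5). camera gave adjusted p = 4.21e-05, and adjusted p = 0.148 with an estimated correlation. Of 11 triglyceride synthesis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), among them Gpat3 (2.73 ± 0.27) and Dgat2 (-0.86 ± 0.12), with camera adjusted p = 0.00593 and adjusted p = 0.159 with an estimated correlation.

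Other lists fell. Among unfolded protein response genes 13 of 16 fell and among interferon response genes 14 of 15. Among cell cycle genes 14 of 19 fell while 1 rose, and among extracellular matrix genes 11 of 14 fell. Their camera adjusted p were 2.62e-06, 1.09e-06, 1.06e-04 and 3.75e-04, and the adjusted p with an estimated correlation were 0.302, 0.302, 0.321 and 0.302. Adjusted over the list alone, 13, 14, 17 and 11 fell and 1 cell cycle gene rose. Sdf2l1 changed by -4.04 ± 0.41, Oasl1 by -2.21 ± 0.30, Mcm5 by -2.78 ± 0.46 and Col3a1 by -3.09 ± 0.30 (log2, SE). Of 12 genes with male-biased expression in liver, 8 fell (8 adjusted over the list alone), among them Hsd3b5 (-7.25 ± 0.91) and Selenbp2 (-5.42 ± 0.62), with camera adjusted p = 7.84e-04 and adjusted p = 0.272 with an estimated correlation. Mup and Cyp4a12 members of that list belong to families of near-identical genes, so their single values are uncertain. Markers of other cell types moved in the same comparison. Of 13 Kupffer cell and macrophage markers 9 fell and 1 rose (11 and 1 adjusted over the list alone). Of 12 lymphocyte markers 6 fell and 1 rose (6 and 1 adjusted over the list alone). Their camera adjusted p were 0.0155 and 0.0303, and the adjusted p with an estimated correlation were 0.627 and 0.302. The call of the lymphocyte list ended without Plin2+/+ fed replicate 4 (adjusted p = 0.0548). Both pancreatic acinar markers tested fell (2 adjusted over the list alone), with log2 fold changes of -2.02 ± 0.23 for Cela1 and -1.97 ± 0.50 for Cela2a (SE), and camera did not call that list (adjusted p = 0.0535; adjusted p = 0.231 with an estimated correlation). Of 8 cholangiocyte markers 5 fell (5 adjusted over the list alone), with camera adjusted p = 0.0174 and adjusted p = 0.302 with an estimated correlation. Of 11 stellate cell markers 5 fell and 1 rose (6 and 2 adjusted over the list alone), and camera did not call that list (adjusted p = 0.464). Of 17 autophagy and lysosome genes 11 rose and 2 fell, and of 16 genes of the insulin, FOXO and glucocorticoid response 9 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.00816 and 0.0145; adjusted p = 0.373 and 0.452 with an estimated correlation).

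By the rule for single genes, the largest rises were those of Adra2a, Cidec, Itga2, Ppp1r3g, Lepr, Eif4ebp3, Apoa4 and Rgs16. Adra2a, an adrenergic receptor, was at 0.0161 ± 0.0360 CPM in fed and 19.2 ± 9.10 CPM in fasted livers (SD, n = 5), so its fold rests on a baseline near 0. Lepr, the leptin receptor, changed by 4.95 ± 0.49 and Apoa4, an apolipoprotein, by 4.63 ± 0.43 (log2, SE). The largest falls were those of Prok1 (-7.36 ± 0.87), Car3 (-7.30 ± 0.60), Hsd3b5, Fdps, Mvd, Selenbp2, Hsd3b2 (-5.35 ± 0.34) and Sqle. Single libraries moved some of these log2 fold changes: that of Adra2a from 9.98 to 12.67 without Plin2+/+ fed replicate 2, of Itga2 from 5.90 to 4.54 without Plin2+/+ fasted replicate 3, of Rgs16 from 4.55 to 5.94 without Plin2+/+ fed replicate 5 and of Ppp1r3g from 5.64 to 6.67 without Plin2+/+ fed replicate 4 and 4.86 without Plin2+/+ fasted replicate 3. That of Prok1 went to -8.0 without Plin2+/+ fasted replicate 5 and that of Hsd3b5 to -7.85 without Plin2+/+ fasted replicate 5.

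The same comparison in Plin2-null mice asked whether the response takes place without PLIN2. All 18 genes of mitochondrial fatty acid oxidation rose, as did 17 of 19 of peroxisomal and omega oxidation, with camera adjusted p = 2.33e-15 and 1.01e-16 and adjusted p = 0.0589 and 0.0589 with an estimated correlation. Adjusted over the list alone the counts were 18 and 18. fry gave adjusted p = 1.64e-09 and 1.64e-09 for these lists, and called 26 of the 44 lists in this comparison. Cpt1a changed by 2.00 ± 0.11, Ehhadh by 4.26 ± 0.19 and Fgf21, a fasting hepatokine, by 4.77 ± 0.64 (log2, SE). Of 25 sterol genes 24 fell (camera adjusted p = 3.03e-21; adjusted p = 0.0683 with an estimated correlation), among them Sqle (-3.62 ± 0.33) and Fdps (-4.47 ± 0.39), and 24 fell adjusted over the list alone. Of 18 fatty acid synthesis genes 13 fell and 4 rose (13 and 4 adjusted over the list alone), with camera adjusted p = 1.13e-04 and adjusted p = 0.247 with an estimated correlation. edgeR called 5896 genes, 2942 higher and 2954 lower in fasted mice, 1988 of them by at least 1 on the log2 scale. With library size alone, 1376 genes rose and 4243 fell, with a shift of the median of all genes of -0.21, and on TPM 945 rose and 4118 fell.

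Lipid droplet and triglyceride genes rose in Plin2-null mice, and over all 5 comparisons these were the only camera calls of a list that held with an estimated correlation. This does not set the genotypes apart. In Plin2+/+ mice camera called both lists as well. On the interaction neither list was called with an estimated correlation or by fry. Of 21 lipid droplet proteins and lipases 14 rose and none fell, with a median log2 fold change of 0.92 (camera adjusted p = 2.98e-09; adjusted p = 0.00821 with an estimated correlation). Of 11 triglyceride synthesis genes 8 rose and 1 fell (camera adjusted p = 6.56e-05; adjusted p = 0.0311 with an estimated correlation). Adjusted over the list alone, 16 and 9 rose. Cidec went from 0.131 ± 0.0885 to 84.3 ± 28.1 CPM and Plin5 from 12.0 ± 3.30 to 140 ± 26.9 CPM (SD, n = 5). By the rule for single genes, the largest rises were those of Cidec, Cgref1 (6.10 ± 0.36), Ly6d (5.25 ± 0.39), Acot2 (4.98 ± 0.28), Aqp4 (4.90 ± 0.35), Apoa4, Fgf21 and Cyp4a14. Among the largest falls were those of Hsd3b5, Car3 (-5.68 ± 0.56), Selenbp2, Hsd3b2, Fdps, Serpina4-ps1 and Gbp10 (-4.21 ± 0.48). Serpina4-ps1 and Gbp10 belong to families of similar genes, so reads may be shared with relatives and their values are uncertain. The log2 fold change of Fgf21 was 5.97 without Plin2-null fed replicate 1, that of Gbp10 -3.62 without Plin2-null fed replicate 2 and that of Hsd3b5, -8.03 with all libraries, -9.09 without Plin2-null fasted replicate 4.

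Other lists called by camera in Plin2-null mice were as follows. Of 6 genes of ketone body synthesis and export 5 rose, of 14 gluconeogenesis genes 8, of 12 integrated stress response genes 5 and of 8 neutrophil and monocyte markers 4, and none of these fell (5, 8, 5 and 5 rose adjusted over the list alone). Their camera adjusted p were 4.56e-04, 6.56e-05, 0.0149 and 0.0262, and the adjusted p with an estimated correlation were 0.182, 0.182, 0.157 and 0.337. Among unfolded protein response genes 10 of 16 fell, among interferon response genes 13 of 15, among cell cycle genes 10 of 19 while 1 rose, among male-biased liver genes 6 of 12, and both pancreatic acinar markers tested (12, 13, 13, 7 and 2 fell adjusted over the list alone, where 1 cell cycle and 1 male-biased gene rose). Their camera adjusted p were 3.07e-05, 9.01e-05, 0.0106, 0.00465 and 0.0176, and the adjusted p with an estimated correlation were 0.367, 0.367, 0.623, 0.293 and 0.108. Of 17 autophagy and lysosome genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0130 and adjusted p = 0.397 with an estimated correlation. Of 14 extracellular matrix genes 5 fell (6 adjusted over the list alone), and of 17 lipoprotein assembly genes 6 rose and 3 fell, the same adjusted over the list alone. These lists had camera adjusted p = 0.0484 and 0.0484 (0.667 and 0.293 as adjusted p with an estimated correlation), and each call ended with several single libraries left out: that of extracellular matrix without Plin2-null fed replicates 1, 2, 3 and 5 (adjusted p = 0.0686, 0.0761, 0.0922 and 0.0552) and without Plin2-null fasted replicates 1, 2, 3 and 4 (adjusted p = 0.0669, 0.0586, 0.0688 and 0.0512), and that of lipoprotein assembly without Plin2-null fed replicates 2, 3 and 5 (adjusted p = 0.0589, 0.0560 and 0.0552) and without Plin2-null fasted replicates 2 and 3 (adjusted p = 0.0576 and 0.0527).

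The responses of both genotypes were then set side by side; they share no library. Of the genes called, 2053 rose in both and 2153 fell in both, against 616 and 641 for independent lists of those sizes, and 5 genes that rose and 5 that fell in Plin2+/+ moved the other way in Plin2-null mice. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.842. The difference itself was tested by the interaction: edgeR called 0 genes, the smallest adjusted p being 0.0602. With 1 library left out, at most 1 was called, which was the count without each of Plin2+/+ fed replicate 1, Plin2+/+ fasted replicate 4, Plin2-null fasted replicate 1 and Plin2-null fasted replicate 2 in turn. At an unadjusted p under 0.05 there were 2250 genes. DESeq2 called 64 and limma voom 0. On simulated counts the interaction test recovered 32.8% of genes changed 2-fold and 78.8% of those changed 4-fold, so part of such differences would be missed at this size. camera called 17 of 44 lists for the interaction, none of them with an estimated correlation (smallest adjusted p = 0.395) and none by fry (smallest adjusted p = 0.0581). camera called 11, 10 and 11 lists without Plin2+/+ fed replicate 4, Plin2+/+ fasted replicate 5 and Plin2-null fasted replicate 2 in turn.

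**Figure D3:**
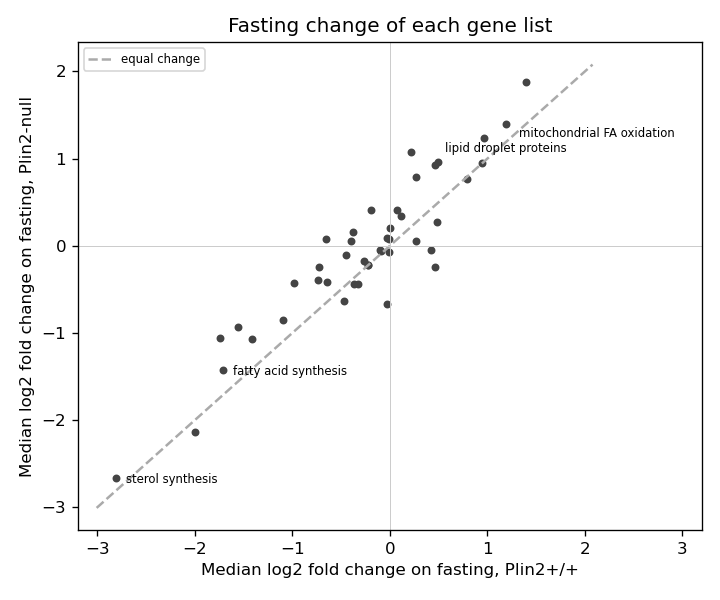
Median log2 fold change on fasting of each of the 44 gene lists in Plin2+/+ (horizontal) and Plin2-null (vertical) livers; the dashed line marks equal change. Sterol synthesis lies at -2.81 and -2.67, lipid droplet proteins at 0.46 and 0.92.

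Few genes differed between genotypes in fed mice. edgeR called 3 genes: Plin2 (-3.72 ± 0.23 SE, adjusted p = 1.30e-09), Mpdz, a scaffold protein of cell junctions (1.09 ± 0.11, adjusted p = 7.75e-06), and the predicted gene Gm13453 (5.40 ± 0.50, adjusted p = 2.52e-06). Gm13453 falls outside the rule for single genes and was chosen after its values were seen; it was at 0.0549 ± 0.0426 CPM in Plin2+/+ and 2.50 ± 1.24 CPM in Plin2-null fed livers (SD, n = 5). Mpdz, on the same chromosome as Plin2 from 81278500 to 81442815, was at 27.8 ± 3.91 CPM in Plin2+/+ and 59.1 ± 3.26 CPM in Plin2-null fed livers (SD, n = 5). At an unadjusted p under 0.05 there were 694 genes, fewer than 5% of the 16312 tested, and DESeq2 called 6. On simulated counts this test recovered 68.7% of genes changed 2-fold. Of the gene lists, camera with its preset correlation called 17 (3 up, 14 down), and none with an estimated correlation (smallest adjusted p = 0.102) or by fry (smallest adjusted p = 0.149). Without Plin2+/+ fed replicate 4 it called 11. camera called the list of female-biased liver genes higher in Plin2-null mice (median log2 fold change 0.60 over 11 genes, camera adjusted p = 3.78e-05; adjusted p = 0.167 with an estimated correlation). It called the lists of male-biased liver genes (-0.68 over 12 genes, camera adjusted p = 5.83e-04), integrated stress response genes (-0.46 over 12, camera adjusted p = 5.50e-04) and unfolded protein response genes (-0.30 over 16, camera adjusted p = 8.14e-06) lower, with adjusted p = 0.225, 0.102 and 0.392 with an estimated correlation. No member of these lists was called among all genes; adjusted over the list alone, 0 female-biased genes were higher, and 4, 1 and 0 of the others were lower. The camera calls of these lists held with each fed library left out. Calls of other lists did not. That of peroxisomal and omega oxidation ended without Plin2+/+ fed replicate 1 (camera adjusted p = 0.640). That of cell cycle genes ended without Plin2+/+ fed replicate 4 (camera adjusted p = 0.307). camera also called lipid droplet proteins and lipases lower (median -0.12 over 21 genes, camera adjusted p = 0.00398; adjusted p = 0.167 with an estimated correlation).

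In fasted mice, the state named in the title of the series, Agpat2, S100a9, H2-Ab1 and Slc25a10 stood higher and Txnip lower in Plin2-null livers. Plin2, Mpdz, Gm13453, Agpat2 and S100a9 were called in fasted mice under each of the 22 alternatives run. Agpat2, an enzyme of triglyceride and phospholipid synthesis, was at 73.9 ± 13.6 CPM in Plin2+/+ and 129 ± 21.2 CPM in Plin2-null fasted livers (SD, n = 5), a log2 fold change of 0.80 ± 0.12 SE with edgeR adjusted p = 0.00383. The neutrophil gene S100a9 was at 1.09 ± 0.304 and 2.92 ± 0.600 CPM (1.42 ± 0.23 SE, adjusted p = 0.00494). H2-Ab1, an MHC class II chain, was higher (1.19 ± 0.19 SE, adjusted p = 0.00494), and its call held with each fasted library left out and ended on unfiltered TPM (adjusted p = 0.0506). Slc25a10, the mitochondrial dicarboxylate carrier, was higher (1.18 ± 0.21 SE, adjusted p = 0.0128), and its call ended without Plin2+/+ fasted replicate 2 (adjusted p = 0.0511) and on unfiltered TPM (adjusted p = 0.0788). Txnip, a thioredoxin-binding protein induced by glucose, was lower (-1.14 ± 0.21 SE, adjusted p = 0.0130), and its call ended without Plin2+/+ fasted replicate 2 (adjusted p = 0.0511) and without Plin2-null fasted replicate 5 (adjusted p = 0.0520), on unfiltered TPM (adjusted p = 0.0532) and with the compared groups alone (adjusted p = 0.0568).

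With all libraries edgeR called 528 genes, 246 higher and 282 lower in Plin2-null mice. Leaving out 1 library moved this count from 13 to 1794. It was 89, 13, 84, 963 and 1794 without Plin2+/+ fasted replicates 1 to 5 in turn. It was 210, 438, 156, 572 and 15 without Plin2-null fasted replicates 1 to 5 in turn. On TPM limma called 18, and DESeq2 called 1430. Library size alone gave 70 higher and 38 lower genes.

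**Figure D4:**
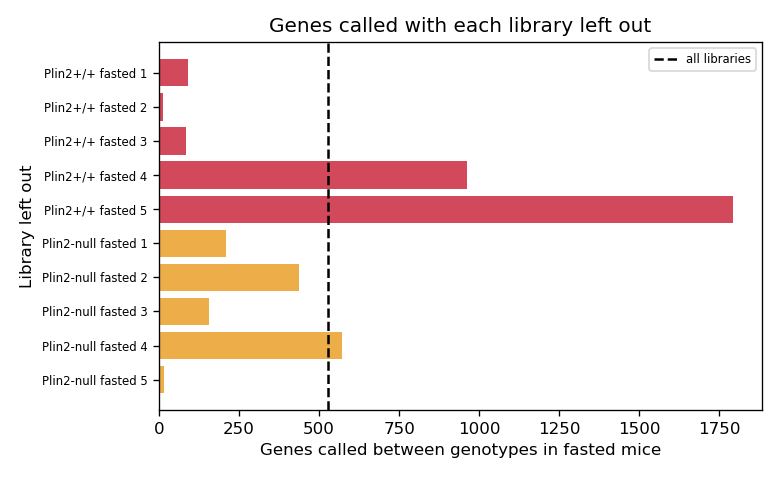
Number of genes called between genotypes in fasted mice (horizontal, bars from 0) with each of the 10 fasted libraries left out in turn; the dashed line is the count with all libraries, 528. The bars run from 13 to 1794.

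GC content and the share of ribosomal RNA were measured beside these genes. The log2 fold change between genotypes in fasted mice went with the GC content of the transcript (Spearman rho 0.426 across genes, which are not independent replicates). The same rho was 0.432 for the interaction, -0.158 for fasting in Plin2+/+, 0.139 for fasting in Plin2-null mice and -0.111 for genotype in fed mice. Genes called higher had a median GC content of 54.4% and genes called lower 44.9%. One gene model with an 18S ribosomal RNA-like sequence, CT010467.1, took 9.11% ± 3.86 of counts in Plin2+/+ and 13.3% ± 6.98 in Plin2-null fasted livers (SD, n = 5; exact two-sided permutation p = 0.302), with a maximum of 24.8% in Plin2-null fasted replicate 3.

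Srebf1 and Sqle, which fell on fasting in both genotypes, stood higher in fasted Plin2-null than in fasted Plin2+/+ livers. Srebf1 was at 5.12 ± 2.08 against 12.4 ± 2.79 CPM (SD, n = 5; 1.28 ± 0.26 SE, edgeR adjusted p = 0.0186). Its call ended without Plin2+/+ fasted replicates 1, 2 and 3 (adjusted p = 0.0585, 0.0630 and 0.0521) and without Plin2-null fasted replicate 5 (adjusted p = 0.0576), and its interaction had adjusted p = 0.216. Sqle, a sterol synthesis enzyme, was at 2.77 ± 0.623 against 7.69 ± 3.36 CPM (1.49 ± 0.33 SE, adjusted p = 0.0270), and its call ended without Plin2+/+ fasted replicates 1, 2 and 3 (adjusted p = 0.0652, 0.0903 and 0.0625) and without Plin2-null fasted replicates 1 and 5 (adjusted p = 0.0577 and 0.0837). Of 25 sterol genes 3 were called higher and none lower (10 higher adjusted over the list alone), with camera adjusted p = 6.72e-05 and adjusted p = 0.709 with an estimated correlation. Of 18 fatty acid synthesis genes 3 were called higher (5 adjusted over the list alone), with camera adjusted p = 0.00362 and adjusted p = 0.709 with an estimated correlation. Of 11 LXR targets 2 were called higher (4 adjusted over the list alone), with camera adjusted p = 0.00669 and adjusted p = 0.616 with an estimated correlation.

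camera called the list of amino acid catabolism and urea cycle genes and that of the insulin, FOXO and glucocorticoid response lower. On fasting in Plin2+/+ mice, 9 of the 16 genes of the latter list were called higher and 1 lower. Of 16 amino acid catabolism and urea cycle genes 2 were called lower (4 adjusted over the list alone), with camera adjusted p = 0.0136 and adjusted p = 0.709 with an estimated correlation. The camera call of that list ended without Plin2+/+ fasted replicate 3 (adjusted p = 0.132) and without Plin2-null fasted replicate 4 (adjusted p = 0.0585). Cps1, the first enzyme of the urea cycle, differed by -0.97 ± 0.23 SE (edgeR adjusted p = 0.0318), and its call ended without Plin2+/+ fasted replicates 2 and 3 (adjusted p = 0.0988 and 0.0870) and without Plin2-null fasted replicates 1, 2 and 5 (adjusted p = 0.0609, 0.0508 and 0.103). Of 16 genes of the insulin, FOXO and glucocorticoid response none was called (3 lower adjusted over the list alone), with camera adjusted p = 0.00362 and adjusted p = 0.709 with an estimated correlation. Adra2a was at 19.2 ± 9.10 against 3.44 ± 3.34 CPM (adjusted p = 0.0145), and its call ended without Plin2+/+ fasted replicate 2 (adjusted p = 0.0523) and without Plin2-null fasted replicate 5 (adjusted p = 0.0520) and with the compared groups alone (adjusted p = 0.0827).

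By the rule for single genes, the largest rises in fasted Plin2-null livers were those of Slc34a2 (2.73 ± 0.59), Oasl1 (1.68 ± 0.30), Mpdz, Cirbp, Tlr12, Srebf1, H2-Ab1 and Slc25a10. The largest falls were those of Plin2, Ppp1r3g (-2.78 ± 0.66), Adra2a, Arl13b (-1.48 ± 0.31), Tbc1d8, Slc25a32, Slc17a8 and Smim13. Calls among these genes ended with single libraries left out: without Plin2+/+ fasted replicate 1, those of Cirbp, Ppp1r3g, Slc17a8, Slc34a2, Tbc1d8 and Tlr12 (adjusted p = 0.0534 to 0.0859), and without Plin2+/+ fasted replicate 2, those of Arl13b, Cirbp, Oasl1, Ppp1r3g, Slc17a8, Slc25a32, Slc34a2, Smim13, Tbc1d8 and Tlr12 (adjusted p = 0.0511 to 0.119), and without Plin2+/+ fasted replicate 3, those of Cirbp, Ppp1r3g, Slc17a8, Slc34a2 and Tbc1d8 (adjusted p = 0.0536 to 0.109). With single libraries of the other genotype left out, calls ended as follows: without Plin2-null fasted replicate 1, those of Ppp1r3g, Slc34a2, Tbc1d8 and Tlr12 (adjusted p = 0.0519 to 0.0758), and without Plin2-null fasted replicate 2, those of Ppp1r3g, Tbc1d8 and Tlr12 (adjusted p = 0.0565 to 0.0622), and without Plin2-null fasted replicate 3, those of Arl13b, Cirbp, Ppp1r3g, Slc17a8, Tbc1d8 and Tlr12 (adjusted p = 0.0508 to 0.0838), and without Plin2-null fasted replicate 5, those of Arl13b, Cirbp, Oasl1, Ppp1r3g, Slc17a8, Slc25a32, Slc34a2, Smim13, Tbc1d8 and Tlr12 (adjusted p = 0.0520 to 0.114). The log2 fold change of Ppp1r3g was -2.01 without Plin2+/+ fasted replicate 3, and that of Adra2a -3.30 without Plin2-null fasted replicate 4. Of the 22 alternatives, these calls held as follows: Tbc1d8 and Tlr12 under 8, Ppp1r3g under 9, Slc17a8 under 13, Cirbp and Slc34a2 under 14, Arl13b under 15 and Oasl1, Slc25a32 and Smim13 under 17.

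Markers of other cell types were tested between genotypes in fasted mice. camera called the lists of Kupffer cell, cholangiocyte and neutrophil and monocyte markers higher (adjusted p = 0.00976, 0.00473 and 0.00362), with adjusted p = 0.709, 0.616 and 0.616 with an estimated correlation. Of 8 neutrophil and monocyte markers 2 were called higher, and of 13 Kupffer cell and 8 cholangiocyte markers none. Adjusted over the list alone, 2, 5 and 0 were higher. Of 11 stellate cell markers 3 were called higher (3 adjusted over the list alone), namely Ngfr, Des and Colec11, whose calls held under 9, 8 and 10 of the alternatives. That of Ngfr ended without Plin2+/+ fasted replicates 1, 2 and 3 (adjusted p = 0.0576, 0.107 and 0.0794) and without Plin2-null fasted replicates 1, 2 and 5 (adjusted p = 0.0669, 0.0652 and 0.0687), that of Des without Plin2+/+ fasted replicates 1 and 2 (adjusted p = 0.106 and 0.135) and without Plin2-null fasted replicates 1, 2, 3 and 5 (adjusted p = 0.0733, 0.0620, 0.0832 and 0.104) and that of Colec11 without Plin2+/+ fasted replicates 1, 2 and 3 (adjusted p = 0.0864, 0.107 and 0.0737) and without Plin2-null fasted replicates 2, 3 and 5 (adjusted p = 0.0577, 0.0640 and 0.0964). camera did not call that list (adjusted p = 0.0522; adjusted p = 0.709 with an estimated correlation). Of 15 interferon response genes only Oasl1 was called (1 adjusted over the list alone), with a median log2 fold change of 0.55, camera adjusted p = 0.00124 and adjusted p = 0.709 with an estimated correlation for the list. The genotype effects of both feeding states shared 2 genes called higher and 1 called lower, and across genes their Pearson r was 0.130. Over all lists camera called 9, and 14 without Plin2-null fasted replicate 3. Among the genes named for this comparison, Srebf1 was called under 15, Sqle under 11 and Cps1 under 11 of the 22 alternatives.

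Xist and the substrain-variable genes served as checks. Xist was at 828 ± 102, 799 ± 174, 906 ± 106 and 626 ± 129 CPM in the order of groups given above (SD, n = 5), and passed the test between genotypes in neither feeding state (adjusted p = 1.00 fed and 0.167 fasted). The substrain-variable genes Nnt, Wdfy1 and Entpd4b did not pass it either (adjusted p = 0.384, 0.232 and 0.244 in fasted mice, and 1.00, 1.00 and 1.00 in fed mice). The log2 fold changes of Entpd4b were 1.56 ± 0.81 in fasted and -0.96 ± 0.74 in fed mice (SE), and its values were 1.27 ± 0.964, 0.397 ± 0.363, 0.642 ± 0.483 and 1.08 ± 1.12 CPM in the same order of groups (SD, n = 5). For the interaction none of the 3 passed among all genes, and adjusted over the list alone 1 was higher and 1 lower.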

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

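The tests on genes near Plin2 and on cell types were chosen only after the results were seen, as were the 18S covariate, the GC trend and the random covariates. Single libraries stood far from the rest of their group in 14 of 118 groups of values. Of these groups 98 held values of chosen genes from the same 20 libraries, some near 0 CPM. They are not independent, and how many chance would set apart was not measured. In CPM unless stated, these were the percent of counts from mitochondrial genes in Plin2-null fasted replicate 4 at 5.34 against 6.46 to 6.89; Adra2a in Plin2+/+ fed replicate 2 at 0.0804 against 0; Adra2a in Plin2-null fasted replicate 4 at 9.30 against 1.51 to 3.15; Itga2 in Plin2+/+ fed replicate 4 at 0.376 against 0.106 to 0.181; Itga2 in Plin2+/+ fasted replicate 3 at 37.9 against 2.36 to 6.12. Others were Ppp1r3g in Plin2+/+ fed replicate 4 at 1.23 against 0 to 0.354, Ppp1r3g in Plin2+/+ fasted replicate 3 at 48.3 against 5.32 to 16.1, Ppp1r3g in Plin2-null fasted replicate 4 at 4.54 against 1.75 to 2.54, Lepr in Plin2+/+ fed replicate 4 at 36.9 against 8.17 to 14.6, Rgs16 in Plin2+/+ fed replicate 5 at 24.6 against 0.884 to 3.85. The rest were Fgf21 in Plin2-null fed replicate 1 at 1.75 against 0.151 to 0.350, Cyp4a14 in Plin2-null fed replicate 4 at 964 against 310 to 375, Plin2 in Plin2-null fed replicate 1 at 32.1 against 15.3 to 17.8, Plin2 in Plin2-null fasted replicate 5 at 130 against 75.1 to 85.4.

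On the interaction, camera with its preset correlation called 17 lists, with these median log2 differences: mitochondrial fatty acid oxidation (0.17), peroxisomal and omega oxidation (0.29), ketone body synthesis and export (0.49), fatty acid synthesis (0.34), sterol synthesis and uptake (0.43), lipid droplet proteins and lipases (0.26), lipoprotein assembly and handling (0.21), integrated stress response (0.55), interferon response (0.44), cell cycle (0.32), extracellular matrix and fibrosis (0.55), female-biased liver genes (-0.33), Kupffer cell and macrophage markers (0.47), cholangiocyte markers (0.83), lymphocyte markers (0.54), neutrophil and monocyte markers (0.60), LXR targets (0.33). None held with an estimated correlation or by fry. Many of these calls also ended with single libraries left out. That of mitochondrial fatty acid oxidation ended without Plin2+/+ fed replicate 1 (camera adjusted p = 0.193), among others. That of Kupffer cell and macrophage markers ended without Plin2-null fed replicate 5 (camera adjusted p = 0.142), among others. Across genes the interaction log2 difference went with GC content (Spearman rho 0.432; genes are not independent replicates).

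Regrouping the libraries asked how often a random split calls as many genes. For fasting, 1 of 100 splits in Plin2+/+ (6957 genes, highest other 2157) and 1 of 100 in Plin2-null mice (5896, highest other 113) called as many genes, the real split included. This is the lowest share that 100 splits can give, so a random split is an unlikely source of these counts. The splits cannot tell feeding from an unrecorded factor that went along with it. For genotype in fasted mice 2 of 100 did, the real split included (528, highest other 781). A regrouping that mixes genotypes called more genes, and leaving out 1 library moved the real count from 13 to 1794. The splits therefore do not settle how much of that count is due to genotype. For genotype in fed mice 6 of 100 splits called as many as the real 3 (highest other 378), and for the interaction 7 of 100 gave as many genes at an unadjusted p under 0.05 as the real 2250 (highest other 4445). Chance is not excluded for these counts. The count in fed mice does not bear on its 3 single genes, Plin2, Mpdz and Gm13453. Each of them was called under all 22 alternatives in both feeding states. The highest split in fed mice called far more genes than the real one, which points to a structure among the fed libraries that was not tested.

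The first pattern weighed is the set of 528 genes called between genotypes in fasted mice. With the GC trend of each library removed, 58.5% of them were still called with the same sign; their median absolute log2 fold change went from 0.67 (median SE 0.16) to 0.55 (median SE 0.14), so the trend may account for part of the calls. With the 18S share as a covariate 31.6% were still called, but 4 of 20 random covariates, a comparison added after that result, kept as few (median 64.2%), and the median absolute fold change moved only to 0.66. An effect of PLIN2 loss, GC-related library bias and RNA quality cannot be told apart for these genes as a set, because the trend with GC varied between libraries of both groups (mean rank correlation of a library's deviations with GC -0.139 ± 0.286 in Plin2+/+ and 0.160 ± 0.163 in Plin2-null fasted livers, SD, n = 5). By library it was -0.422, -0.408, -0.0987, -0.0239 and 0.259 in Plin2+/+ fasted replicates 1 to 5. In Plin2-null fasted replicates 1 to 5 it was -0.00609, 0.0126, 0.157, 0.376 and 0.258. Called genes numbered 89 and 13 without Plin2+/+ replicates 1 and 2, the lowest of their group, and 1794 without replicate 5, the highest. They numbered 572 without Plin2-null replicate 4, the highest of its group, and 15 without replicate 5.

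The second pattern is a possible excess of genotype differences near Plin2, noticed before it was tested from Mpdz, called in both feeding states, Ccdc171, called in fasted mice alone, and Ttc39b, called in neither. In fed mice 4 of 48 genes within 10 Mb of Plin2 had an unadjusted p under 0.01, and without those 3 genes 1 of 45 did, against 0.928% of other genes (one-sided Fisher exact p = 0.344; odds ratio 2.42, 0.0597 to 14.4 as 95% interval). In fasted mice 4 of 48 were called, Mpdz and Ccdc171 among them, and 2 of 45 without the genes seen first, against 3.22% of other genes. A candidate explanation is that DNA flanking the targeted locus differs between the genotypes, by a passenger segment or a local effect of the targeting; Mpdz lies on chromosome 4 from 81278500 to 81442815 (GENCODE M21, GRCm38) and Gm13453 on another chromosome. This and an effect of PLIN2 loss that ignores position cannot be told apart here, because the interval of the odds ratio is wide and holds both.

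The third pattern is that H2-Ab1, an antigen presentation gene, and Ms4a1, a B cell gene, stood higher in fasted Plin2-null livers, while the lymphocyte list was not called (camera adjusted p = 0.154, 1 of 12 genes). Ms4a1 was called under 8 of 19 alternatives, and its call ended without Plin2+/+ fasted replicates 1, 2 and 3 (adjusted p = 0.107, 0.118 and 0.103) and without Plin2-null fasted replicates 3, 4 and 5 (adjusted p = 0.0704, 0.0758 and 0.115). If a lower share of hepatocytes were the whole cause, markers of every other type would rise by about as much as these genes. The Kupffer cell, stellate, cholangiocyte and lymphocyte lists differed by 0.45 ± 0.15, 0.29 ± 0.06, 0.61 ± 0.21 and 0.44 ± 0.16 (SE). The sinusoidal endothelial list differed by -0.04 ± 0.06. Together, the lists other than lymphocytes differed by 0.33 ± 0.07 against 1.25 ± 0.29 for H2-Ab1 and Ms4a1, a gap of -0.92 ± 0.25 taken per library. This gap was taken up after the permutation result below was known. It cannot decide the question, because H2-Ab1 and Ms4a1 were picked for their rise. Of 10 pairs of marker lists 4 lay over 2 standard errors apart, at most 3.49 for Kupffer cell against sinusoidal endothelial markers (exact permutation p of the largest 0.0952 over 252 rearrangements). B cell markers differed by 1.02 ± 0.44 and T and NK cell markers by 0.03 ± 0.18, a difference of 0.99 ± 0.56. A lower share of hepatocytes, more lymphocytes and a change within cells cannot be told apart with 5 livers per group. A response to PLIN2 loss stays open and untested.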

How the results depend on the processing

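The 18S covariate and the GC trend were added after seeing the data. The total of genes called stayed within 1.5 times under every alternative for both fasting comparisons, but their direction depended on the scaling. Genes called higher fell from 3416 to 1494 in Plin2+/+ and from 2942 to 945 in Plin2-null mice on log2(TPM + 1). With library size alone they fell to 1854 and 1376. The strong counts of both comparisons fell to 1246 and 1163 on log2(TPM + 1), and to 1216 and 1140 without a TPM filter, where the added 1 shrinks folds of low genes. Genotype in fed mice gave 6 genes (5 strong) by DESeq2 and 7 (5 strong) on unfiltered TPM. Genotype in fasted mice gave 1430 (219 strong) by DESeq2, 108 (58) with library size alone, 319 with no filter, 18 (10), 13 (12) and 10 (7) on log2(TPM + 1), log2(TPM + 0.1) and unfiltered TPM, 104 (49) with the compared groups alone, which have fewer samples, and 173 (69) with the 18S covariate; otherwise the cause was not tested. With 1 library left out it ranged from 13 to 1794 (8 to 322 strong). The interaction gave 64 (38 strong) by DESeq2, 1 (1) with no filter, 1 (1) on unfiltered TPM, and 0 to 1 (0 to 1 strong) with 1 library left out. With an estimated correlation, 0 and 2 lists were called for fasting in Plin2+/+ and Plin2-null, and 0, 0 and 0 for genotype fed, genotype fasted and the interaction. fry called 28 and 26 for fasting in Plin2+/+ and Plin2-null, and 0, 3 and 0 for the last 3. With 1 library left out, camera called 11 to 19, 8 to 14 and 10 to 18 lists for these. No called gene or list that was checked under the alternatives changed sign, and Ccdc171 was not among those checked. Depth, at least 25506471 counts per library, limits genes near 0 CPM, such as Adra2a in fed livers. No paired analysis was possible because the replicate numbers follow the order of the samples and carry no pairing.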

Other observations

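Gapdh, often used as a reference gene, was at 38.3 ± 48.2, 9.07 ± 1.57, 4.91 ± 1.67 and 105 ± 91.6 CPM in Plin2+/+ fed, Plin2+/+ fasted, Plin2-null fed and Plin2-null fasted livers (SD, n = 5). Gapdh ranged widely within the Plin2+/+ fed and the Plin2-null fasted group. It was chosen after its values were seen, and it has many processed copies in the genome, so its value is uncertain.

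Ccdc171 and Ttc39b also lie near Plin2 and were chosen after their values were seen. Ccdc171 stood lower in Plin2-null livers, at 6.32 ± 1.81 against 1.77 ± 0.298 CPM in fasted mice (SD, n = 5; edgeR log2 fold change -1.84 ± 0.21 SE, adjusted p = 4.02e-05); in fed mice its log2 fold change was -0.80 ± 0.20 (adjusted p = 0.742). Ttc39b passed the test in neither state: it stood at 57.9 ± 4.91 against 89.1 ± 12.8 CPM in fed mice (adjusted p = 0.0714), and its log2 fold change in fasted mice was 0.18 ± 0.12 (adjusted p = 0.350).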
